A study of Mus musculus with 95 samples.

How the data were processed

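Small RNA was measured by sequencing in 95 libraries from 32 mice aged 6 months. The mice were heterozygous zQ175 knock-in (KI) animals, a mouse model of Huntington's disease, and wild type (WT) littermates on a C57BL6/J background. Per the labels, 2 lines were used: CHDI-81003003, in which a neomycin resistance (neo) cassette was intact, and CHDI-81003019, from which it was deleted. The labels name 3 tissues: left striatum, left cortex and the left lobe of the liver. Per the labels' protocols, tissue was flash-frozen, total RNA was extracted with a Qiagen RNeasy kit, and libraries were made from enriched RNA fractions with Illumina protocols. Tissue, line and genotype gave 12 groups of 8 animals, 4 of each sex, except that the striatum of neo-deleted KI mice had 7. KI and WT mice with the same replicate number were different animals, while the tissues of 1 animal shared its identifier.

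The deposited count table held estimated counts per feature for 1881 features, not scaled for library size. The deposited FPKM table held fragments per kilobase of feature and 1000000 counts, equal to the count over the feature's length and the library's total. Dividing one table by the other gave a length per feature that was constant within 0.5 nt in all 415 features with a rounded count in any library, and 1466 features had none. Per the submitters' processing notes, CASAVA 1.8.2 and the mouse assembly mm10 were used. The aligner, the counting method and the feature reference were not given in the sources used here. Of 22592 estimates of at least 1, 6469 (28.6%) were not whole within a tolerance of 0.005. Of the 415 features, 281 had whole estimates in all libraries, and those of the others were not whole in some library. Why estimates were not whole was not tested. Features carried identifiers of the form MI and 7 digits, which the files did not pair with names or positions. None of these identifiers was found in the reference tables used here, which listed 1228 mouse miRNA genes. The sources used here do not state from which species the features were taken, so an identifier stands for the entry to which reads were assigned and not for a known mouse gene. If the entries are those of another species, counts cover only mouse reads that matched them. The 18 miRNA lists and the miRNA names fixed in advance therefore could not be applied, and no genomic position is given.

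Total counts per library ran from 74540 to 496035 (median 124029), and all libraries together held 19014092 counts. Each library's name in the labels also holds a number after the letter L, called the L number here. The labels do not say what the number stands for. The 26 libraries with L number 8 (L8) had a median total of 419439 and the other 69 a median of 117174.

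Counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16, using trimmed-mean (TMM) scaling and filterByExpr (minimum count 10, minimum total 15) by group. The quasi-likelihood test was applied at a Benjamini-Hochberg adjusted p under 0.05, and a feature past it is said to be called. Each tissue was fitted on its own with its 4 groups of line and genotype and with sex as a covariate. The filter left 188 features in striatum, 186 in cortex and 131 in liver, with 99.8%, 99.9% and 99.8% of the counts. The same fits gave the contrasts of KI and WT in each line, the difference between the lines' KI effects, WT mice between lines, and sex. Sex by genotype was fitted with 8 groups. The KI effect in striatum minus that in cortex was fitted in both tissues of each line, and tissues were compared in WT mice with sex and line as covariates. These comparisons, their tests and most alternatives were fixed before the data were examined. Levels are TMM-scaled counts per 1000000 (CPM), given as mean ± SD over libraries. SE is that of the log2 change from the quasi-likelihood fit, which includes variation between libraries, unless stated otherwise. P values are two-sided unless stated. Floors cover counting error only, and reads without molecular identifiers are not independent molecules. A floor is 3 counts over the libraries of a group, and floors and the levels set beside them are CPM of total counts without TMM scaling.

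Lists of striatum-enriched and cortex-enriched features were made from WT mice of the line not being compared, at adjusted p under 0.05 and a log2 difference of at least 1. They were tested with limma 3.58.1 by camera with a preset correlation of 0.01, by camera with an estimated correlation, and by fry, adjusted over the lists of a comparison. fry tests whether a list moves 1 way on balance and does not compare it with other features.

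Settings varied as fixed in advance were DESeq2 size factors in edgeR, total counts only, no filter, at least 10 CPM in 7 libraries, DESeq2 1.42.0, limma voom with quality weights, limma on log2 FPKM with 1 or 0.1 added, no sex term, the replicate number as a block of 8 levels, only the 2 groups compared, 1 sex only, each library left out, and the L number as a factor. The replicate numbers do not pair KI with WT animals: per tissue and line, the residuals of 0 to 2 KI animals correlated best with the WT animal of their own number. Residuals of the same animal had a mean correlation of -0.0934 between striatum and cortex (31 animals) and 0.00358 between liver and cortex (32 animals). Chosen after the data were seen were combinations of the L number with the other choices, fits within 1 L number, the L number in the sex and tissue contrasts, L8 as a covariate when lists were made, a liver and cortex contrast without L8 libraries, and the removal of 2 cortical libraries. The fits with and without the L number are both given where they differ. The pipeline was tested on simulated data made from the libraries, with 40 changed features in each of 5 runs. Simulated means and dispersions came from fits with sex and the L number, so the fit with the L number matched them by construction. The simulated rates therefore do not decide which fit suits the real data.

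Features were named by a shortened form of a rule fixed in advance. The miRNAs that the fixed rule named were dropped because names were missing. That the shortened rule names fewer features per direction, and none that were not called, was a separate choice. Per comparison the shortened rule names the 2 that rose and the 2 that fell with the largest log2 change among those called without the L number. In tissue contrasts it names only those with a mean of at least 100 CPM. No value column of the tables was left unused, and 0 of 329 pairs of libraries compared within groups were identical.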

Results

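Small RNA counts were compared between zQ175 KI and WT mice in striatum, cortex and liver, in a line with the neo cassette intact (neo-intact) and a line without it (neo-deleted). Each group held 8 animals except neo-deleted KI striatum, with 7. The median total count per library was 129192 in striatum (31 libraries), 136017 in cortex (32) and 111605 in liver (32). Libraries had counts in 174 to 301 features, with a median of 244. In striatum, MI0000472 took 19.1% ± 4.01 of the counts (SD, n = 31) and MI0000289 (estimates not whole) took 9.91%. In cortex the same features led, with 16.5% ± 3.56 (SD, n = 32) for MI0000472 and 11.7% for MI0000289. In liver, MI0000234 took 19.7% ± 2.34 (SD, n = 32) and MI0000093 (estimates not whole) took 10.7%. The 10 most abundant features of a tissue held 57.4% of the counts in striatum, 58.7% in cortex and 70.3% in liver.

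The 3 tissues differed widely in WT mice. This describes the tissues but does not check their labels, since without names no known tissue marker could be looked up. MI0000274, an identifier with an implied length of 109 nt, was the feature furthest above cortex in striatum among those with a mean of at least 100 CPM. It stood at 4668 ± 2010 CPM in striatum and 115 ± 121 CPM in cortex (n = 16 each). In striatum against cortex, 95 of 191 features were called, 56 higher and 39 lower in striatum, and 113 had an unadjusted p under 0.05. The log2 difference of MI0000274 was 5.44 (SE 0.30, adjusted p = 6.08e-21). MI0003938 (112 nt) was also higher in striatum, at 666 ± 224 against 179 ± 278 CPM, with a log2 difference of 2.07 (SE 0.32, adjusted p = 1.60e-06). MI0000267 (110 nt) was lower, at 23.6 ± 19.4 against 162 ± 81.3 CPM (log2 -2.44, SE 0.38, adjusted p = 4.30e-07). MI0000272 (110 nt) was lower too, at 1269 ± 759 against 4613 ± 7050 CPM (log2 -1.87, SE 0.45, adjusted p = 0.000470), with -1.20 when the animal was a block (adjusted p = 0.0240). L7 libraries were striatal and the L1 and L2 libraries of the brain were cortical, so that the tissues could be compared within an L number only in L8 (5 striatal and 7 cortical libraries). There edgeR called 90 features, 45 in each direction. The 4 named features stayed called within L8, with MI0000274 at log2 4.99 (adjusted p = 7.99e-05), MI0003938 at 1.963 (adjusted p = 0.0440), MI0000267 at -2.64 (adjusted p = 3.29e-05) and MI0000272 at -1.81 (adjusted p = 0.000998).

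Liver differed from cortex in 177 of 191 features, 59 of them higher and 118 lower in liver. The median log2 difference of all features was -1.55 with TMM scaling and -1.44 with DESeq2 size factors. L8 libraries were 7 of the 16 cortical and 0 of the 16 liver libraries, and without them 181 features were called (65 higher and 116 lower, median -1.20). MI0017383 (73 nt, estimates not whole) stood at 33925 ± 6594 CPM in liver and 6.68 ± 14.03 CPM in cortex (log2 13.05, SE 0.53, adjusted p = 9.86e-28, and log2 11.42 without L8 libraries). MI0000234 (110 nt, estimates not whole) stood at 234589 ± 27166 and 759 ± 158 CPM (log2 8.27, SE 0.14, adjusted p = 2.46e-43). MI0000466 and MI0000468, whose estimates were not whole, had no count in the 16 liver libraries. These libraries held 1618934 counts, so that 3 counts correspond to 1.85 CPM. With 5534 ± 5106 CPM in cortex, MI0000466 was at least 2987-fold lower in liver (adjusted p = 1.64e-08). Over the 9 cortical libraries that were not L8 it averaged 1450 ± 1894 CPM, at least 783-fold above liver. With 5245 ± 2069 CPM, MI0000468 was at least 2830-fold lower (adjusted p = 7.06e-21), and at least 3336-fold lower than in those 9 libraries.

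Libraries with L number 8 differed from the others in most features. L8 libraries were in striatum and cortex only, where the other numbers were mostly L7 and L1. In striatum, 159 of the tested features were called between L8 and L7 (88 higher and 71 lower in L8), and 151 when all libraries were thinned to 1 depth. In cortex, 131 of 186 were called between L8 and L1 (73 higher and 58 lower). The L8 differences of the 2 tissues correlated across 182 features (r = 0.979, rho = 0.923), though features are not independent replicates. MI0007261 and MI0007262 (62 nt each, estimates not whole) had no count in the 69 other libraries, which held 7912070 counts, so that 3 counts correspond to 0.379 CPM. They averaged 1813 ± 727 and 1358 ± 674.2 CPM in the 26 L8 libraries, at least 4781-fold and 3582-fold higher. KI and WT groups held unequal numbers of L8 libraries. Striatal L8 libraries were 5 of 8 KI and 1 of 8 WT in the neo-intact line and 4 of 7 KI and 4 of 8 WT in the neo-deleted line. Cortical L8 libraries were 0 of 8 KI and 4 of 8 WT in the neo-intact line and 5 of 8 KI and 3 of 8 WT in the neo-deleted line.

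In striatum, KI mice of both lines had less MI0000274 and MI0000288 and more MI0000271 than their WT littermates. MI0000274 was also the feature most enriched in striatum over cortex in WT mice, as given for the tissues. Each of these 3 changes was called in both lines with and without the L number. No alternative that was run with the L number ended the call of MI0000274 in either line, or those of MI0000288 and MI0000271 in the neo-deleted line. With the L number in the model, 29 features were called in the neo-intact line (14 higher and 15 lower in KI, 44 at an unadjusted p under 0.05). The neo-deleted line also gave 29 calls (16 higher and 13 lower, 57 at an unadjusted p under 0.05). Without the L number, 22 were called in the neo-intact line (9 higher and 13 lower, 62 at an unadjusted p under 0.05) and 10 in the neo-deleted line (1 higher and 9 lower, 18 at an unadjusted p under 0.05). Of these, 14 of 22 and 10 of 10 stayed called in the same direction with the L number. The share of higher calls moved with the scaling. Without the L number, DESeq2 size factors gave 17 higher and 13 lower in the neo-intact line. With the L number, they gave 18 higher and 10 lower in the neo-intact and 28 higher and 12 lower in the neo-deleted line, while total counts gave 10 higher and 22 lower, and 14 higher and 22 lower. The biological coefficient of variation in striatum was 0.397 without the L number and 0.182 with it. In simulated data for the neo-intact line, 19.02% of calls were false without the L number and 4.32% with it, and 2-fold changes were called in 70.8% and 87.7% of cases. For the neo-deleted line, 0% and 3.66% of calls were false, and 1.5-fold changes were called in 55.7% and 87.1% of cases. Because the simulated data contained the L number differences, the fit with the L number had an advantage by construction.

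MI0000274 stood at 2018 ± 1083 CPM in neo-intact KI mice and 6153 ± 1751 CPM in WT mice (n = 8 each). The log2 change was -1.62 (SE 0.33, adjusted p = 0.00132), and -1.01 with the L number (SE 0.10, adjusted p = 2.86e-09). In the neo-deleted line it stood at 1740 ± 706 in KI (n = 7) and 3966 ± 2129 CPM in WT (n = 8). The log2 change there was -1.17 (SE 0.34, adjusted p = 0.0364), and -0.96 with the L number (SE 0.09, adjusted p = 3.45e-09). Within L7, KI and WT means were 3304 ± 349 (n = 3) and 6721 ± 757 CPM (n = 7) in the neo-intact line and 2449 ± 406 (n = 3) and 5928 ± 534 CPM (n = 4) in the neo-deleted line. Within L8 they were 1246 ± 73.4 (n = 5) and 2181 CPM (n = 1), and 1208 ± 93.3 (n = 4) and 2003 ± 124.2 CPM (n = 4). Every KI library lay below every WT library of its line and L number. The neo-deleted call without the L number was lost, at adjusted p between 0.0746 and 0.188, when any 1 of 10 libraries was left out. These were KI M2, M4, F1, F2, F3 and F4 and WT F1, F2, F4 and M3.

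MI0000288 (110 nt) stood at 1003 ± 104 CPM in neo-intact KI and 1826 ± 242 CPM in WT mice (n = 8 each), with a log2 change of -0.86 (SE 0.11, adjusted p = 5.48e-06). Including the L number gave -0.68 (SE 0.08, adjusted p = 2.33e-07). The neo-deleted means were 954 ± 169 (n = 7) and 1638 ± 298.9 CPM (n = 8). The log2 change was -0.78 (SE 0.12, adjusted p = 3.38e-05), and -0.75 with the L number (SE 0.08, adjusted p = 8.52e-09). The KI libraries below every WT library numbered 8 of 8 and 7 of 7. MI0000288 was named by the shortened rule in the neo-deleted line only, as was MI0000271 (110 nt, estimates not whole), and their neo-intact values are given for comparison. MI0000271 stood at 3345 ± 566 against 2108 ± 398 CPM in the neo-intact line (log2 0.67, SE 0.12, adjusted p = 0.000197). Including the L number gave 0.45 (SE 0.06, adjusted p = 3.83e-06). In the neo-deleted line it stood at 3462 ± 380.5 against 2464 ± 515 CPM (log2 0.52, SE 0.12, adjusted p = 0.00624), with 0.48 when the L number was included (SE 0.06, adjusted p = 4.21e-07). KI libraries above the WT mean numbered 8 of 8 and 7 of 7, but those above every WT library of their line only 5 of 8 and 5 of 7.

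**Figure D1:**
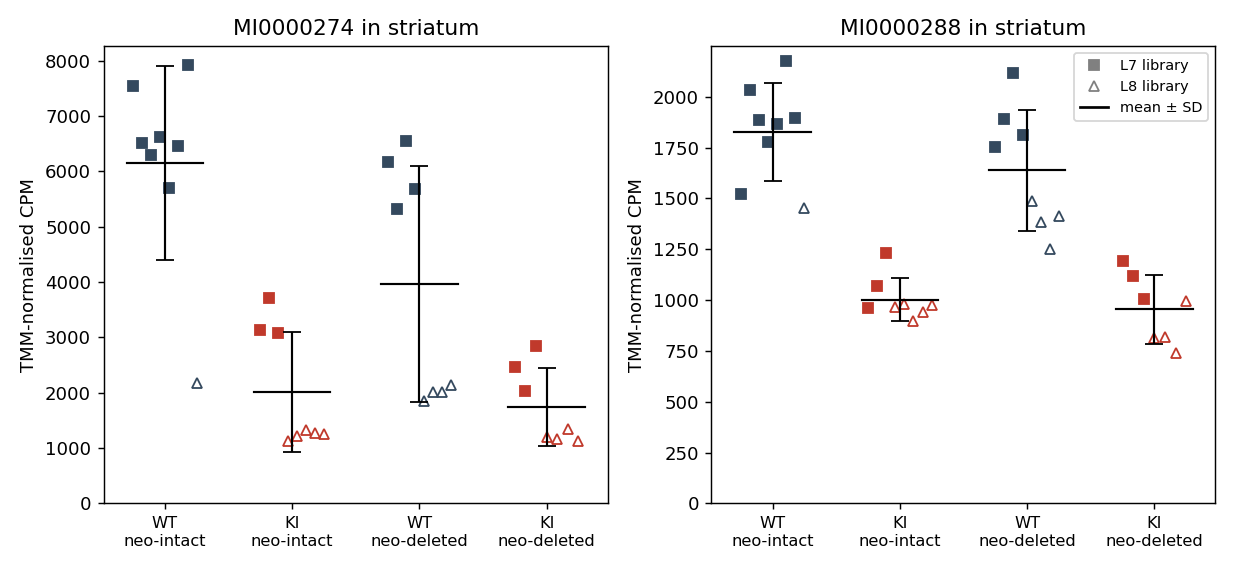
TMM-scaled CPM of MI0000274 and MI0000288 in each striatal library of the 4 groups, with squares for L7, triangles for L8, and mean ± SD. MI0000274 averaged 2018 CPM in KI and 6153 CPM in WT mice of the neo-intact line, and 1740 and 3966 CPM in the neo-deleted line.

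The shortened rule named 3 more features in the neo-intact striatum, and these depended more on the L number. MI0000542 (82 nt, estimates not whole) stood at 963 ± 581 in KI and 2018 ± 525 CPM in WT mice (log2 -1.10, SE 0.36, adjusted p = 0.0435). Including the L number gave -0.45 (SE 0.09, adjusted p = 0.000537). The neo-deleted line gave no call without the L number (log2 -0.36, adjusted p = 0.973) or with it (log2 -0.21, adjusted p = 0.0942). MI0000086 (86 nt, estimates not whole) stood at 80.8 ± 24.97 against 40.8 ± 18.3 CPM (log2 0.96, SE 0.27, adjusted p = 0.0217), and was not called with the L number (log2 0.58, SE 0.22, adjusted p = 0.0728). MI0000748 (82 nt) stood at 73.2 ± 30.7 against 37.5 ± 21.6 CPM (log2 0.91, SE 0.30, adjusted p = 0.0435), and was not called with the L number (log2 0.50, SE 0.25, adjusted p = 0.223). Without the L number, MI0000542 lost its call, at adjusted p of 0.0636 to 0.103, when any 1 of 12 libraries was left out, which were KI M2, M3, M4, F3 and F4 and WT F1, F2, F3, F4, M1, M2 and M4. MI0000748 lost it at 0.0536 to 0.108 without any 1 of the same libraries except WT F1. MI0000086 lost it at 0.0591 to 0.0596 without KI F3 or WT M4, and with the L number it gained a call at 0.0180 to 0.0314 without KI F2 or WT F2, F4 or M1.

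The count of striatal calls without the L number moved with single libraries. In the neo-intact line, 22 calls became 54 without KI M1 or without WT M3, 48 without KI F2 and 40 without KI F1. They became 14 without KI M3 or WT F3, 13 without KI M4, KI F4 or WT M2, and 12 without KI F3, WT F2 or WT M4. The 10 neo-deleted calls became 6 without KI M2, KI M4 or KI F1 and 5 without WT F1. With the L number the counts stayed between 21 and 30 in the neo-intact line and between 25 and 42 in the neo-deleted line. Within L7 alone, 13 features were called in the neo-intact line (3 KI, 7 WT) and 8 in the neo-deleted line (3 KI, 4 WT). Within L8, 31 were called in the neo-deleted line (4 KI, 4 WT) and 3 in the neo-intact line, where WT had 1 library.

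The lines share no animals, and each was fitted on its own with the L number to compare their calls over the 177 features tested in both. Of 12 and 23 features that rose, 10 were shared, where 1.56 were expected by chance (Fisher's exact test, one-sided p = 1.02e-08). Of 10 and 12 that fell, 7 were shared, where 0.678 were expected (Fisher's exact test, one-sided p = 9.17e-08). Both p values treat features as independent and equally likely to be called, and do not measure variation between animals. None was called in opposite directions. Of the shared features, MI0000272 had the largest log2 change, at 1.79 in the neo-intact and 1.14 in the neo-deleted line. It was picked after its values were seen. The log2 changes correlated across features (r = 0.503, rho = 0.558), which are not independent replicates.

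**Figure D2:**
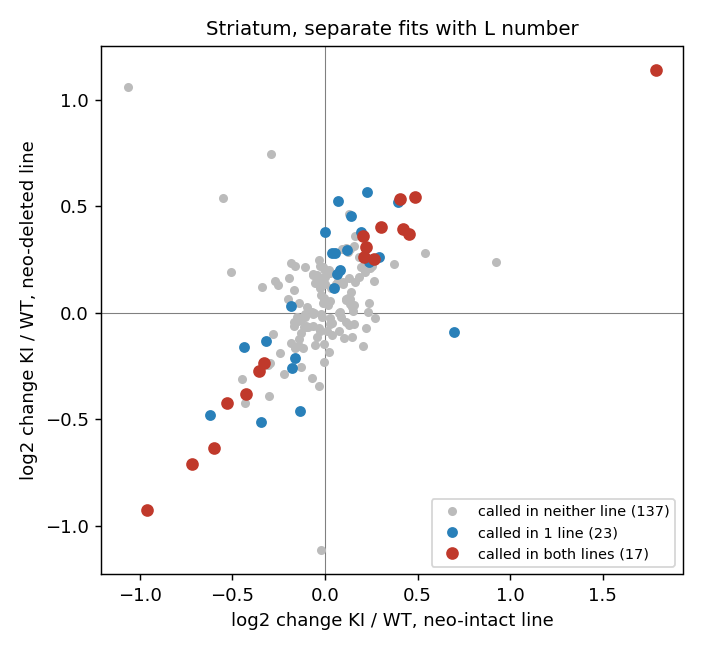
Log2 change of KI over WT in striatum for 177 features in the neo-intact line (x axis) and the neo-deleted line (y axis), each line fitted on its own with the L number. Features called in both lines (17) changed in the same direction, and 23 were called in 1 line.

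As a list, features enriched in striatum over cortex had a median change below 0 in the striatum of KI mice of both lines, though most members were not called on their own. The first values are from fits without the L number. Of the 17 measured in the neo-intact line, 0 rose and 5 fell, or 7 fell adjusted over the list alone. The median log2 change was -0.25 and the mean -0.24 (camera, adjusted p = 0.00777). The call held with an estimated correlation (adjusted p = 0.0307), and fry gave an adjusted p = 3.01e-05. The fit with the L number gave a median of -0.16 and an adjusted p = 0.000241 (0.0227 with an estimated correlation). In the neo-deleted line, 3 of 13 fell and 0 rose, with 3 adjusted over the list alone, a median of -0.19 and a mean of -0.21 (camera, adjusted p = 0.00804). That call did not hold with an estimated correlation (adjusted p = 0.330), and fry gave an adjusted p = 0.153. The fit with the L number gave a median of -0.11 and an adjusted p = 0.0188, which again did not hold with an estimated correlation (0.166), while fry gave 0.000398. A list of 9 made with L8 as a covariate, chosen after the data were seen, was called downward without the L number (camera, adjusted p = 0.00466). That call held with an estimated correlation (adjusted p = 0.0207) and by fry (adjusted p = 0.000435). With the L number these 3 tests gave 0.000552, 0.0145 and 1.73e-07. Each of the striatum-enriched lists includes MI0000274, which was called on its own in both lines. In the neo-deleted line with the L number its log2 change was -0.96, while the list of 9 had a mean of -0.12. The list tests were not repeated without MI0000274, so they do not show a shift of the other members. Cortex-enriched features gave no call in striatum, with 8 measured in the neo-intact line (median 0.13, mean 0.11, adjusted p = 0.879, test direction down) and 15 in the neo-deleted line (1 rose, adjusted p = 0.175). A neo-deleted cortex-enriched list made with L8 as a covariate, chosen after the data were seen, was called upward in striatum (13 measured, 1 rose, camera, adjusted p = 0.0313). That call held with an estimated correlation (adjusted p = 0.0306) and by fry (adjusted p = 0.000435). With the L number camera gave an adjusted p = 0.0411, and 0.0612 with an estimated correlation. The neo-intact list made in that way gave 0.520 by camera and 0.0403 by fry without the L number. In cortex none of these lists was called. The adjusted p values were 0.260 for both lists in the neo-intact line, where 3 of 16 striatum-enriched and 1 of 9 cortex-enriched features fell. The neo-deleted line gave 0.0586 for the striatum-enriched list (13 measured, median -0.24) and 0.445 for the cortex-enriched list.

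The series holds lines with and without the neo cassette, so the difference between their KI effects was tested directly. In striatum edgeR called 0 features (6 at an unadjusted p under 0.05) and DESeq2 0. The fit with the L number called 1, MI0024976, chosen after its values were seen, with a difference of -0.88 (SE 0.19, adjusted p = 0.0101; 9 at an unadjusted p under 0.05). In cortex edgeR called 0 (85 at an unadjusted p under 0.05), and 0 with the L number (13 at an unadjusted p under 0.05), while DESeq2 without it called 31. In liver edgeR called 0 (8 at an unadjusted p under 0.05) and DESeq2 0. Between WT mice of the lines, edgeR called 0 features in striatum (23 at an unadjusted p under 0.05) and 0 in cortex (8 at an unadjusted p under 0.05). In liver it called MI0000267, at 111 ± 42.6 CPM in the neo-deleted and 495.9 ± 238 CPM in the neo-intact line (log2 -2.14, SE 0.51, adjusted p = 0.0314). This feature was not called with the L number (log2 -2.03, adjusted p = 0.0689).

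In cortex, differences between KI and WT followed the L numbers. All 8 neo-intact KI libraries were L1, while the WT libraries were L1 (3), L2 (1) and L8 (4). Without the L number edgeR called 18 features in the neo-intact line (2 higher and 16 lower in KI, 76 at an unadjusted p under 0.05), with a smallest adjusted p of 0.0482. With the L number it called 0 (15 at an unadjusted p under 0.05), as did DESeq2 (18 at an unadjusted p under 0.05) and voom (14 at an unadjusted p under 0.05). Within L1, with 8 KI and 3 WT libraries, it called 0 (11 at an unadjusted p under 0.05). In simulated data for this comparison, 32.7% of calls were false without the L number and 4.57% with it, and 2-fold changes were called in 69.2% and 83.1% of cases. As in striatum, the simulation contained the L number differences, which favours the fit with the L number. Total counts gave 10 higher and 60 lower and moved the median log2 change of all features from -0.07 to -0.28, FPKM gave 10 higher and 28 lower with a median of -0.26, DESeq2 gave 15 higher and 26 lower, and DESeq2 size factors in edgeR gave 0 (75 at an unadjusted p under 0.05). Leaving out 1 library moved the 18 calls to 52 (WT F3), 41 (WT M1), 30 (WT M4), 9 (KI F2), 3 (KI M3), 1 (KI M2) or 0 (KI M1, M4, F3 or F4, or WT F1, F2, F4 or M2).

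MI0000762 (65 nt) stood at 114 ± 34.3 CPM in neo-intact cortical KI mice and 48.3 ± 28.2 CPM in WT mice (log2 1.44, SE 0.47, adjusted p = 0.0482). WT libraries of L1 averaged 64.9 ± 14.2 CPM (n = 3) and those of L8 25.5 ± 13.9 CPM (n = 4), and the change with the L number was 0.59 (adjusted p = 0.470). MI0002469 (73 nt) stood at 785 ± 212.4 against 533 ± 159 CPM (log2 0.57, SE 0.18, adjusted p = 0.0482). WT libraries of L1 averaged 697 ± 137.8 CPM and those of L8 435 ± 56.99 CPM, and the change with the L number was 0.28 (adjusted p = 0.470). MI0007261 and MI0007262 fell, with no count in the KI libraries and in the 4 WT libraries that were not L8. They averaged 1529 ± 241 and 831 ± 552 CPM in the 4 L8 WT libraries. The calls of these 4 features were lost, at adjusted p of 0.0511 to 0.141, when any 1 of 11 libraries was left out: KI M1, M2, M3, M4, F2, F3 or F4, or WT F1, F2, F4 or M2. In the neo-deleted cortex edgeR called 0 features (6 at an unadjusted p under 0.05), DESeq2 0 (9) and voom 36 (13 higher and 23 lower), and with the L number edgeR called 0 (9 at an unadjusted p under 0.05).

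**Figure D3:**
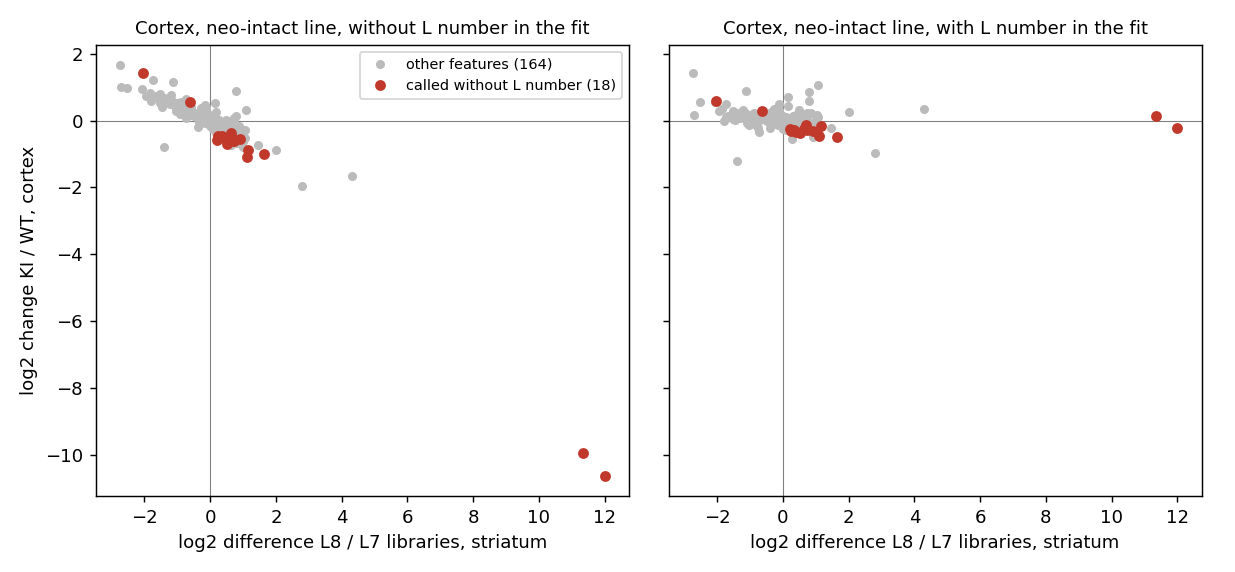
Log2 change of KI over WT in neo-intact cortex against the log2 difference between L8 and L7 libraries in striatum, for 182 features, fitted without and with the L number. The 18 features called without the L number lie opposite in sign to their L8 difference, and none is called with it.

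Whether the KI effect differed between striatum and cortex was tested in each line. In the neo-deleted line, edgeR called 1 feature, MI0002468 (79 nt), with a difference of -0.74 (SE 0.17, adjusted p = 0.0305; 11 at an unadjusted p under 0.05). With the animal as a block it called 0 (6 at an unadjusted p under 0.05). With the L number, 5 were called, 1 higher and 4 lower in striatum, among them MI0002468 (log2 -0.80, adjusted p = 0.00148). MI0000288 (log2 -0.52, adjusted p = 0.00378) and MI0000271 (log2 0.37, adjusted p = 0.0310) were also called and were picked after their values were seen. With both the L number and the animal as a block, 2 features were called. In the neo-intact line, 107 of 186 were called without the L number (53 higher and 54 lower, 120 at an unadjusted p under 0.05), where L8 libraries lie mostly on the KI side in striatum and on the WT side in cortex. The fit with the L number called 0 (14 at an unadjusted p under 0.05). MI0002470 (68 nt, estimates not whole) and MI0000762 had the largest differences among called features lower in striatum, at -2.92 and -2.49. Among those higher, MI0007261 and MI0007262 had the largest fitted values, for which no fold is given because they have counts in L8 libraries only.

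In liver, no feature was called between KI and WT mice with edgeR. The neo-intact line gave 0 calls (11 at an unadjusted p under 0.05; DESeq2 0, voom 1), and 2 without KI F2. The neo-deleted line gave 0 (3 at an unadjusted p under 0.05; DESeq2 0, voom 0). In simulated data for these comparisons, 2-fold changes were called in 87.7% of cases in the neo-intact line and 93.8% in the neo-deleted line, and 1.5-fold changes in 52.9% and 62.9%.

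Male and female livers differed clearly, while the brain regions showed no called sex difference. In liver, 20 of 131 features were called, 11 higher and 9 lower in males (34 at an unadjusted p under 0.05). The fit with the L number also called 20, 10 in each direction. In WT libraries alone (8 of each sex), 2 were called, MI0000077 and MI0006382 (21 at an unadjusted p under 0.05). MI0000077 (72 nt) stood at 37823 ± 8085 CPM in males and 15905 ± 2277 CPM in females (n = 16 each; log2 1.25, SE 0.08, adjusted p = 1.15e-13). MI0000478 (89 nt) stood at 119 ± 43.1 and 34.7 ± 17.1 CPM (log2 1.73, SE 0.23, adjusted p = 7.60e-07). MI0006382 was lower in males, at 97.0 ± 42.5 against 549 ± 135 CPM (log2 -2.50, SE 0.18, adjusted p = 4.66e-13). MI0003906 (94 nt) was lower at 313 ± 174.7 against 728 ± 202 CPM (log2 -1.28, SE 0.21, adjusted p = 2.97e-05), though not in WT libraries alone (log2 -1.01, adjusted p = 0.114). In striatum edgeR called 0 (10 at an unadjusted p under 0.05), and in cortex 0 (15 at an unadjusted p under 0.05).

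**Figure D4:**
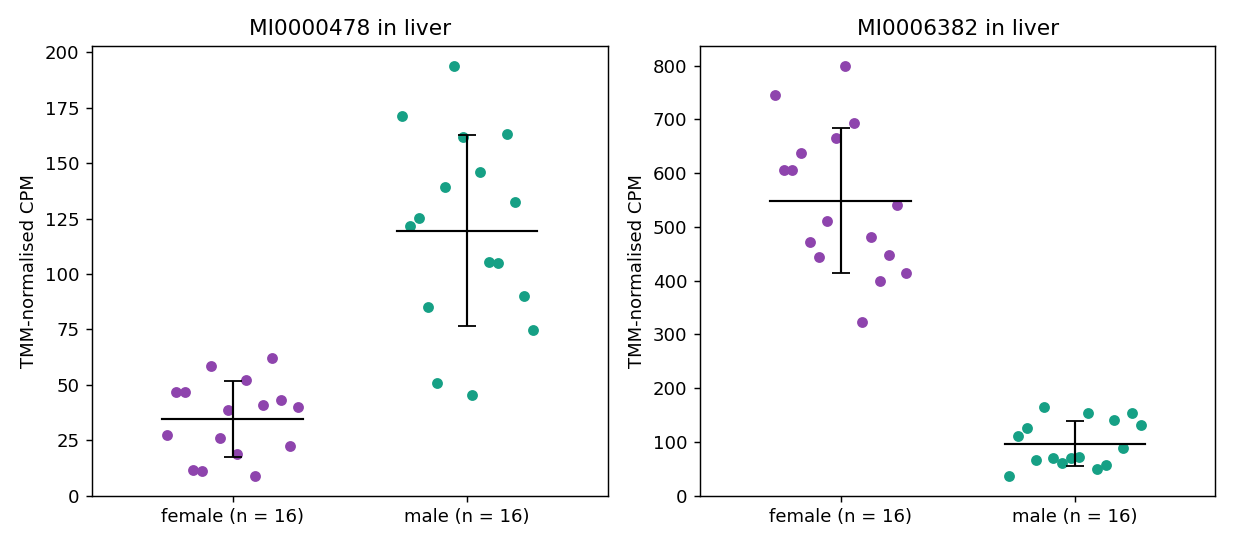
TMM-scaled CPM of MI0000478 and MI0006382 in each liver library of 16 females and 16 males, with mean ± SD. MI0000478 averaged 119 CPM in males and 34.7 CPM in females, and MI0006382 averaged 97.0 and 549 CPM.

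The KI effect was not found to differ between the sexes. The test of sex by genotype in edgeR called 0 features in each tissue and line. At an unadjusted p under 0.05 it gave 2 features in striatum, 4 in cortex and 9 in liver in the neo-intact line, and 4, 2 and 3 in the neo-deleted line. With the L number it also called 0, and these counts were 12, 10 and 10, and 16, 8 and 3. The smallest adjusted p was then 0.0818, in neo-deleted striatum. Groups held at most 4 animals of a sex, and the median SE in striatum without the L number was 0.389 and 0.398. Differences between the sexes could therefore be missed.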

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

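The tests of L numbers, of cortical tissue in striatal samples, of the size of thinned changes and of reads from other libraries were chosen only after the result was seen. Of 60 groups of 4 to 10 libraries tested with Dixon's rule for a library far from the others, 6 had one, and the rule picks about 1 in 20 groups by chance.

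The striatal changes of KI mice were found in both lines, with 17 features called in the same direction and 0 in opposite directions when each line was fitted on its own with the L number. An imbalance of L numbers between KI and WT as the whole cause is argued against by these 17, by the 14 of 22 neo-intact calls that stayed called with the L number, and by KI libraries below WT libraries within each L number for MI0000274. Depth as the whole cause is argued against by thinning to 103873 counts per library, after which 24 features were called in the neo-intact and 29 in the neo-deleted line with the L number. Cortical tissue in the KI samples would need a share of 51.96% and 49.7% to lower MI0000274 as observed and would raise cortex-enriched features by a median log2 of 0.76 and 0.70, against 0.0430 (SE 0.10) and 0.13 (SE 0.08) observed over 11 and 13 features of lists made with L8 as a covariate. Striatum-enriched features moved in the direction that cortical tissue would give, with medians of -0.16 (SE 0.07) and -0.16 (SE 0.12) over 15 and 8 features, against -0.40 and -0.56 needed. The SEs of these medians come from a bootstrap of a median over features. Features are not independent replicates, so these SEs do not measure variation between animals. With the L number, 5 of the 11 and 4 of the 13 cortex-enriched features had a change below 0. MI0000272, a member of both lists, rose by log2 1.79 and 1.14 in the separate fits of the lines. A smaller share of cortical tissue is not excluded. An effect of the KI allele, directly or through a change in cell composition or health of the animals, stays open and was not tested further.

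The cortical calls of the neo-intact line ran against the L8 difference seen in striatum, with r = -0.998 across the 18 called features, all moving the opposite way, and r = -0.955 without the pair counted in L8 libraries only. Over all features r was -0.944 and rho -0.848, and r was -0.245 with the L number in the model. These values are consistent with the L numbers of the KI libraries, all L1, as the source of the calls, and no feature was called with the L number. Depth alone is not settled: after thinning to 106899 counts per library, 5 features were called, all among the 18, while the smallest adjusted p went from 0.0482 to 0.0497 and the features at an unadjusted p under 0.05 from 76 to 67. The median absolute log2 change of the 18 went from 0.586 (median SE 0.177) to 0.571 (median SE 0.180), so that thinning ended calls at the edge of the threshold with little change in size.

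Cortical neo-intact WT libraries F1 (L8) and F3 (L1) had high MI0000274, at 286 and 550 CPM, against medians of 55.1 CPM over 11 other L8 and 83.1 CPM over 18 other L1 libraries. Striatal tissue in the cortical sample would need a share of 8.88% in F1 and 11.9% in F3. The other 15 striatum-enriched features averaged 0.56 higher in F1, where 0.18 was needed, and 0.20 higher in F3, where 0.24 was needed, with an SD over the other libraries of 0.16 and 0.12. In F1 all 15 were higher and in F3 11 were. The mean in F3 lay near the amount needed, so striatal tissue may explain F3 but was not separated from other sources. The mean in F1 was above the amount needed by more than the SD over the other libraries. A striatal share of 8.88% alone therefore does not account for F1. Reads of striatal libraries assigned to the wrong library stay open as well: 0 striatal libraries had the L number of F3 and 14 that of F1, and the labels do not say what the number means. No biological explanation was tested.

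The total count of neo-intact striatal WT M3 was 441412, against a median of 111151 in the rest of its group, and it was the only L8 library there. The same library had the lowest MI0000274 of its group, at 2181 CPM against a median of 6516 CPM. Its MI0000542 was 777 CPM against 2182 CPM. Neo-intact striatal KI F2 had 27.9 CPM of MI0000086 against 90.5 CPM. Neo-deleted liver KI M2 had 748 CPM of MI0000267 against 118 CPM. Neo-deleted liver KI M1 had 146223 CPM of MI0000234 against 192767 CPM.

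Tests of a difference between groups called 1 feature for the striatal KI effect between lines with the L number. The KI effect in striatum minus cortex gave 107 calls in the neo-intact line without the L number. The neo-deleted line gave 1 call without the L number and 5 with it.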

How the results depend on the processing

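Fits within 1 L number, DESeq2 with the L number, the L number in the striatum minus cortex contrast and removal of 2 cortical libraries were chosen only after the result was seen. Leaving single libraries aside, 46 alternatives moved a count of calls by over 1.5 times. MI0000274 in both lines, MI0000288 and MI0000271 in the neo-deleted line and MI0000542 in the neo-intact line kept direction and call in every alternative run with the L number. Without it, MI0000274 lost its call in 2 neo-intact and 17 neo-deleted alternatives, MI0000271 in 5 neo-deleted ones and MI0000288 in 1. Low counts limit features near the filter, and names fixed for 18 lists could not be applied.

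Separate fits are given as counts, which need not hold the same features. Against 22 striatal neo-intact calls, other fits gave 14 with no filter, 35 with DESeq2, 140 with voom, 3 in males, 1 in females, 13 within L7 and 3 within L8, and leaving out 1 library gave 12 to 54. Against 10 neo-deleted calls, they gave 6 with total counts, 5 with no filter, 6 on log2 FPKM with either pseudocount, 4 with only the 2 groups, 1 in males, 2 in females and 31 within L8. The L number gave 29, or 47 with DESeq2, and leaving out 1 library gave 5 to 10. Within 1 sex or 1 L number fewer libraries were tested, which does not account for the rise to 31 within L8. The cause of these moves was not tested.

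Against 18 cortical neo-intact calls, edgeR gave 0 with DESeq2 size factors (75 at an unadjusted p under 0.05), no filter (97), 10 CPM in 7 libraries (78), the L number (15), males (19), females (57) and L1 only (11). Other fits gave 70 with total counts, 41 with DESeq2, 102 with voom, 38 on log2 FPKM with either pseudocount and 1 without WT F1 and F3, and leaving out 1 library gave 0 to 52. MI0007262 went from log2 -9.94 to 0.14 with the L number. Against that 0.14, it reversed to -0.41 with the replicate block added and to -0.17 without WT F2 (up to 0.51 without other libraries). MI0007261 went from -0.23 with the L number to 0.0129 with the block added. Both have counts in L8 libraries only, so these fits cannot estimate them. In neo-deleted cortex voom called 36. The cause was not tested beyond the L number.

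With the replicate block, the 18 cortical calls became 0 in edgeR (71 at an unadjusted p under 0.05), while striatal calls were 15 and 9. The numbers do not pair the animals. With the animal as a block, the neo-deleted striatum minus cortex count of 1 became 0 in edgeR (6 at an unadjusted p under 0.05), and 2 with the L number too. It was 0 with no filter (16) and 5 with the L number. The neo-intact count of 107 became 0 with the L number (14) and with both (16).

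In neo-intact liver, voom, both FPKM settings and males alone gave 1 call against 0, and leaving out 1 library gave 0 to 2. The striatal line difference rose to 1 with the L number, DESeq2 called 31 for the cortical one, and the liver WT line difference fell to 0 in edgeR (9 at an unadjusted p under 0.05) with the L number. Sex in liver gave 2 calls in WT libraries only, where fewer were tested. The neo-deleted striatum-enriched list made without L8 as a covariate went from a camera p of 0.00402 to 0.165 with an estimated correlation and 0.0763 by fry. The cause was not tested.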

Other observations

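The tests of other groupings of the same libraries were set before the result was seen. In each, 100 splits into groups of the same sizes were fitted, the reported grouping included.

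With the L number in the model, only the reported split reached the 29 striatal calls of the neo-intact line (highest other 8). The same held for the 29 of the neo-deleted line (highest other 17). Without the L number, the neo-intact 22 were reached by 3 splits (highest other 38), and the split with 38 divided L8 libraries 5 against 1, as the reported grouping does. The neo-deleted 10 were reached by 2 (highest other 67, with L8 divided 6 against 2). The counts of 38 and 67 point to a structure of the samples that follows L8, so the counts without the L number are not read as set apart from it. For the 18 neo-intact cortical calls, 1 split reached the count (highest other 8), but the reported grouping itself divides L8 libraries 0 against 4, and edgeR called 0 with the L number (15 at an unadjusted p under 0.05).

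Where 0 features were called, all 100 splits reach 0 by construction, which says nothing about chance. The highest other counts show how many calls a split can give. They were 3 for neo-intact cortex with the L number, 83 for neo-deleted cortex without it (L8 divided 1 against 7) and 1 with it, 7 for neo-intact and 1 for neo-deleted liver. They were 1 and 3 for the line difference in striatum and liver and 56.99% of the tested features for that in cortex. They were 26 and 12 for WT lines in striatum (L8 divided 5 against 0) and cortex (L8 divided 6 against 1). For sex they were 1 in striatum and 1 in cortex. For sex by genotype they were 1 and 93 in striatum, 3 and 75 in cortex and 14 and 1 in liver, neo-intact first. The splits with 83, 93 and 75 calls and that for the cortical line difference point to a structure of the samples.

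Only the reported split reached the count for sex in liver (20 calls, highest other 10). The same held for the contrasts of striatum and liver with cortex (95 and 177 calls, highest other 69 and 100). The splits with 69 and 100 calls divided L8 libraries 10 against 2 and 5 against 2. The WT liver line difference (1 call) was reached by 4 splits (highest other 1), and the call was lost with the L number in edgeR (0 calls, 9 at an unadjusted p under 0.05). For striatum minus cortex, splits moved both tissues of an animal together. The neo-intact 107 calls were reached by 1 split (highest other 33), but L8 is divided unequally there and the L number left 0 calls in edgeR (14 at an unadjusted p under 0.05). The neo-deleted call was reached by 2 splits (highest other 4), and with the animal as a block it was lost in edgeR (0 calls, 6 at an unadjusted p under 0.05). Neither the liver line call nor these tissue differences are settled by the splits.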
